A study of Mus musculus with 8 samples.

How the data were processed

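RNA was sequenced from 8 mouse cell libraries, 4 titled EXO and 4 titled LPS, with replicate numbers 1 to 4 in each group. Per the labels' protocols, total RNA was extracted with TRIzol, its integrity was checked on a Bioanalyzer, and libraries were made with the VAHTS Universal V6 kit. Per the submitters' processing notes, HISAT2, a spliced read aligner, and the mouse build GRCm39 (mm39) were used. The tool that assigned fragments to genes, its strand setting, the annotation release and the HISAT2 version are not given in the sources used here.

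The authors deposited 1 table of 18473 genes, 14226 protein-coding and 4247 non-coding, with an FPKM value (fragments scaled to the length of the gene and to the depth of the library) for each of the 8 libraries and annotation columns with Entrez gene numbers, KEGG pathways and GO terms. Its header names no unit. The unit FPKM was inferred from the values, which are not whole numbers, sum to between 544225 and 621034 per library, and step within each gene by whole multiples of a unit that depends on the gene and the library. All per-sample columns in the table belong to these 8 libraries. A total of 828 genes had a value of 0 in all libraries.

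Library depth was recovered from those steps. For 17643 of the 17645 genes detected in at least 1 library (99.99%), every value came out as a whole number of fragments, with a largest distance from a whole number of 0.001. The recovered totals were 37601341, 39187983, 37061712 and 37083166 fragments for EXO replicates 1 to 4, and 40640973, 38760778, 40640131 and 39686553 for LPS replicates 1 to 4. Short genes of low FPKM rest on few fragments, S100a8 for example on 26 at 1.79 FPKM in EXO replicate 4. The recovered counts were used for depth, for a search for duplicated libraries and for an alternative test, not for the main test.

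The planned main test assumed raw counts. Because the table held FPKM, the fallback written beside it before the data were examined was used. Values were transformed to log2(FPKM + 1), genes with an FPKM of at least 1 in at least 4 libraries were kept (9812 genes, 9479 protein-coding and 333 non-coding), and EXO was compared with LPS in limma 3.58.1 under R 4.3.3, with an intensity trend and robust empirical Bayes variances. Tests were two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Effects are EXO minus LPS. A fold change on the log2(FPKM + 1) scale understates the change of genes with low values, so group means in FPKM are printed beside it. Nothing in the labels says that the replicates were separate cultures, so the p-values measure the spread between these samples, which may be technical.

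Before the data were examined, 37 lists were fixed: 21 pathway lists, 3 quality lists and 13 lists of cell type markers. Of the pathway and quality lists, the 22 with at least 5 tested genes were compared with all other tested genes by camera in limma with a preset correlation between genes of 0.01, adjusted over those 22 lists. The same lists were tested by camera with the correlation estimated from the data, and by fry, a rotation test of whether the genes of a list move, on balance, in a direction. The 35 splits of the 8 libraries into 4 and 4 gave an exact two-sided permutation p for each list's median fold change, whose smallest possible value is 0.029. That permutation was added after the data were seen. A list is described as shifted where camera with the preset correlation passed the threshold. List members were matched to the table by symbol or, for 18 entries, by Entrez number, and 73 list entries are not analysed here.

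The genes named in the text follow a rule fixed before the data were examined. It takes Irf7 and Nlrp3, which the series title names. It adds the 10 highest and the 10 lowest log2 fold changes among genes with an adjusted p under 0.05, a mean FPKM of at least 1 and no overlap between the groups, leaving out predicted genes and pseudogenes. It also takes up to 4 members of each list with the smallest p, and the 3 highest members of each cell type list. Genes outside the rule are said to have been chosen after their values were seen. Some genes that the rule takes are not reported here.

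Alternatives included a pseudocount of 0.1, no filter on low values, a mean FPKM of at least 5, median-of-ratios rescaling of the FPKM, voom on the recovered counts, a spline correction for GC content and gene length, the replicate number as a block, and leaving out each library in turn. Another alternative left out EXO replicate 2 and LPS replicate 4 together, the libraries nearest the other group on the first principal component. Those that were chosen after the data were seen are named in the closing section. The gene annotation used for GC content and chromosome is of another build (GRCm38) than the authors', so it served for names and base composition, and no coordinates are printed. GC content was known for 9685 of the tested genes (98.7%).

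The tests were checked on data simulated from the means and depths of the real libraries for EXO against LPS, with 200 genes changed and 9784 genes tested. The fit recovered 46.3% of genes changed by 1.5-fold, 92.4% of those changed by 2-fold and 100% of those changed by 4-fold, and 8 of its 166 calls were false (4.8%). In the real comparison 58.4% of tested genes were called, a far larger share, on which the adjustment depends. These recovery rates therefore need not hold for the real test. In a separate simulation of 20 lists of independently drawn genes, camera found the 1 shifted list and called 0 of the others at an adjusted p under 0.05. Genes of real lists were correlated, with an estimated correlation of 0.569 for the interferon-stimulated genes. The simulation does not show how often camera calls such lists falsely. Tables were handled in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.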

Results

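Gene expression was measured by RNA sequencing in 8 libraries of mouse cells, 4 titled EXO and 4 titled LPS. The design text speaks of macrophages treated with ADSC-Exos and asks which genes change with macrophage polarization, the adoption of inflammatory or reparative states, and the series title adds Irf7 and Nlrp3. The abbreviations are not spelled out in the labels. LPS usually stands for lipopolysaccharide, a bacterial cell wall component that activates macrophages, and ADSC-Exos usually stands for exosomes, small secreted vesicles, of adipose-derived stem cells. No label says whether the EXO libraries also received LPS, at which dose or for how long, and untreated cells are not analysed here. Between 37061712 and 40640973 fragments per library were assigned to genes. Values below are mean FPKM ± SD over the 4 libraries of a group, and fold changes are EXO minus LPS on the log2(FPKM + 1) scale.

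The libraries carried the expression profile of macrophages, while the labels name MLE-12, an immortalized mouse lung epithelial line. Of 18 general macrophage markers, 17 had a mean of at least 1 FPKM. Lyz2, the macrophage lysozyme, reached 3357 ± 523 in EXO and 9969 ± 3819 in LPS. Fcer1g and Tyrobp, adaptors of activating immune receptors, stood at 1059 ± 78.7 and 782 ± 71.8 in EXO, against 2152 ± 338 and 1563 ± 447 in LPS. Of 13 general epithelial markers, the 2 analysed were Ocln and Elf3. Ocln, a tight junction protein, was listed at 0 in all EXO libraries and averaged 0.0058 ± 0.012 in LPS, and Elf3, an epithelial transcription factor, averaged 0.0033 ± 0.0066 in EXO and was listed at 0 in all LPS libraries. The other markers of that list, keratins and claudins among them, are not analysed here.

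Among 5 analysed markers of alveolar type 2 epithelium, 4 had a mean of at least 1 FPKM, and all 4 are also expressed outside epithelium. Napsa, an aspartic protease, averaged 32.5 ± 3.05 in EXO and 57.5 ± 12.1 in LPS, Abca3, a lipid transporter, 5.56 ± 1.12 and 12.7 ± 2.34, and Etv5, a transcription factor, 8.20 ± 1.86 and 3.38 ± 0.970. Lpcat1, a lysophospholipid acyltransferase, averaged 4.21 ± 0.646 and 6.30 ± 1.29. Of 10 analysed markers of alveolar macrophages, the lung's resident macrophages, Fabp4, a fatty acid carrier, alone had a mean of at least 1 FPKM over the 8 libraries, at 4.90 ± 1.90 in EXO and 11.9 ± 2.77 in LPS. Marco, a scavenger receptor, averaged 0.554 ± 0.1 and 1.23 ± 0.733, and Atp6v0d2 0.0632 ± 0.0536 and 0.475 ± 0.284.

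Markers of other cell types were low, apart from single genes. Of 7 analysed endothelial markers, Egfl7 alone reached a mean of 1 FPKM. It averaged 12.9 ± 1.96 in EXO and 3.03 ± 0.750 in LPS, while the endothelial adhesion molecule Pecam1 stayed at 0.155 ± 0.109 and 0.177 ± 0.109 and Vwf at 0.0775 ± 0.0296 and 0.162 ± 0.0379. Of 7 analysed neutrophil markers, 2 reached it. Csf3r averaged 1.45 ± 0.442 and 5.63 ± 1.24, S100a8 3.84 ± 1.66 and 2.76 ± 1.5, and Camp 0.318 ± 0.239 and 0.800 ± 0.564. Of 4 analysed T and NK cell markers Il7r alone reached it, and of 7 dendritic cell markers Batf3 alone. Il7r averaged 5.29 ± 1.57 and 7.59 ± 2.46, and Batf3 5.85 ± 1.53 and 5.86 ± 1.17. None of 5 analysed markers of alveolar type 1 cells, 3 of club and ciliated cells, 6 of fibroblasts and stroma, 2 of B cells and 3 of erythroid cells reached it. Among them the stromal marker Eng had the highest mean over the 8 libraries, at 0.465 ± 0.0870 in EXO and 0.281 ± 0.0425 in LPS. Of 4 tested sex-linked genes 2 fell and 2 were not called, over all genes and adjusted over the list alone. Ddx3y, on the Y chromosome, averaged 17.6 ± 3.18 and 22 ± 3.23, Uty 2.98 ± 0.822 and 4.84 ± 0.765, Eif2s3y 13.2 ± 1.68 and 16.6 ± 1.80, and Kdm5d 3.56 ± 0.374 and 3.44 ± 0.338. The call of Eif2s3y (limma adjusted p = 0.0414) was lost without any of EXO replicates 1 and 4 or LPS replicates 2 and 3 (0.0998 to 0.137), without a filter on low values (0.0641) and after a GC content and length correction (0.298), and the sign of Kdm5d turned under rescaling (-0.045). Ddx3y was called without EXO replicate 3 or LPS replicate 1 (limma adjusted p of 0.0270 and 0.0442) and under rescaling (0.0195), and Il7r without LPS replicate 1 (0.0152).

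The general macrophage markers were themselves lower in EXO in most cases. Of 17 tested, 13 fell, 1 rose and 3 were not called, with a median log2 fold change of -0.84. Adjusted over the list alone, 13 fell and 2 rose. Csf1r, the receptor for the macrophage growth factor, averaged 98.4 ± 13.8 in EXO and 333 ± 68.9 in LPS (log2 fold change -1.74, SE 0.15, limma adjusted p = 5.36e-07). Fcgr1, an Fc receptor for antibodies, averaged 26.1 ± 2.59 and 71.3 ± 11.2, and Ptprc (CD45), the pan-leukocyte phosphatase, 37.0 ± 7.79 and 95.7 ± 9.22. The lower immune gene lists moved beside this lower level of macrophage markers.

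**Figure D1:**
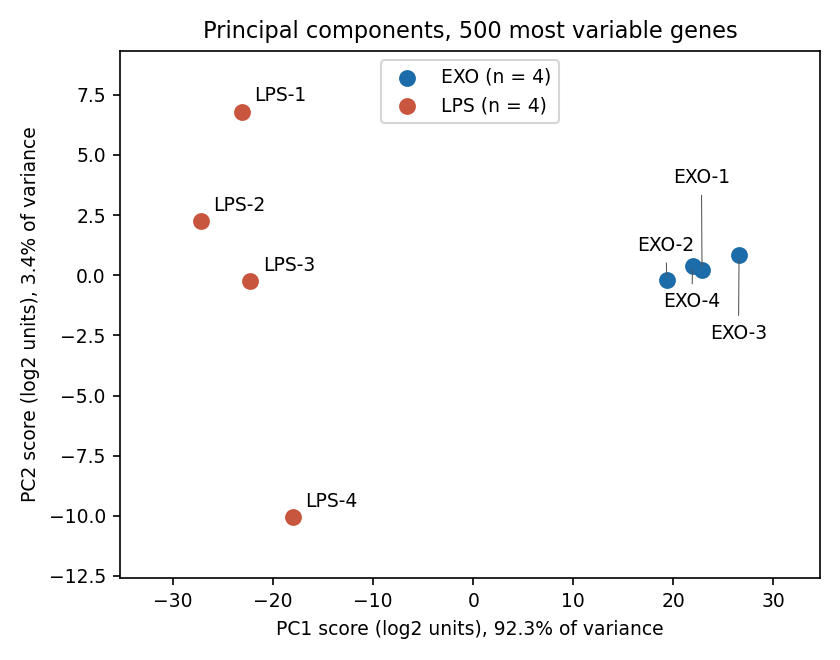
First against second principal component of log2(FPKM + 1) for the 500 most variable genes, both in log2 units, with each point a library (blue EXO, red LPS, n = 4 each). The first component carries 92.3% of the variance and separates the groups, and LPS replicate 4 lies at -18.05 on it and at -10.05 on the second.

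The libraries separated by group on the first principal component, which held 92.3% of the variance. EXO libraries scored from 19.3 to 26.6 and LPS libraries from -27.2 to -18.1. Across genes, libraries of the same group correlated with Pearson's r from 0.979 to 0.994 and libraries of different groups with r from 0.903 to 0.948, genes not being independent replicates. LPS replicate 4 stood nearest to the EXO group and apart from the other LPS libraries on the second component, at -10.05. On that component the LPS libraries also fell in order of replicate number, with replicates 1 to 3 at 6.8, 2.25 and -0.24. Some macrophage markers fell in the same order over LPS replicates 1 to 4. Lyz2 stood at 14930, 10500, 8580 and 5859 FPKM and Csf1r at 425, 331, 316 and 259, while Fcgr1 and Ptprc did not follow it. The source of that order was not tested. No libraries looked duplicated, since the counts of same-group pairs differed by a chi-square of at least 37.9 per degree of freedom.

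Of 9812 genes tested, 3310 were higher and 2422 were lower in EXO than in LPS at a limma adjusted p under 0.05, and 4080 were not called. Of these, 509 were higher and 636 lower by at least 1 on the log2 scale. At an unadjusted p under 0.05 the counts were 3571 and 2587. Under median-of-ratios rescaling the balance turned, with 2849 higher and 2975 lower. The groups did not overlap in 5028 genes (51.2%), where chance gives 2.86%. Among 333 non-coding genes tested, 77 were higher and 115 lower.

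Irf7 (Entrez gene 54123), an interferon-induced transcription factor that drives type I interferon transcription, was lower in EXO. It averaged 11.4 ± 6.76 in EXO and 143 ± 15.9 in LPS, 12.6 times higher in LPS by mean FPKM. The EXO libraries stood at 17.9, 5.81, 5.28 and 16.6 FPKM and the LPS libraries at 123, 159, 139 and 151. The log2 fold change was -3.72 (SE 0.38, 95% confidence interval -4.59 to -2.84, limma adjusted p = 6.73e-05, 4 of 4 EXO libraries below every LPS library).

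Nlrp3 (Entrez gene 216799), the sensor protein of the inflammasome that activates caspase-1, did not differ detectably. It averaged 22.1 ± 3.57 in EXO and 22.4 ± 6.22 in LPS, with a log2 fold change of 0.0048 (SE 0.17, 95% confidence interval -0.36 to 0.37, limma adjusted p = 0.983). EXO libraries ranged from 17.4 to 25.3 FPKM and LPS libraries from 17.5 to 31.5, the highest being LPS replicate 4. The sign turned under median-of-ratios rescaling (-0.097) and when any of EXO replicates 3 and 4 or LPS replicates 1, 2 and 3 was left out, and without EXO replicate 2 and LPS replicate 4 the value was 0.28 with a limma adjusted p of 0.0484.

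**Figure D2:**
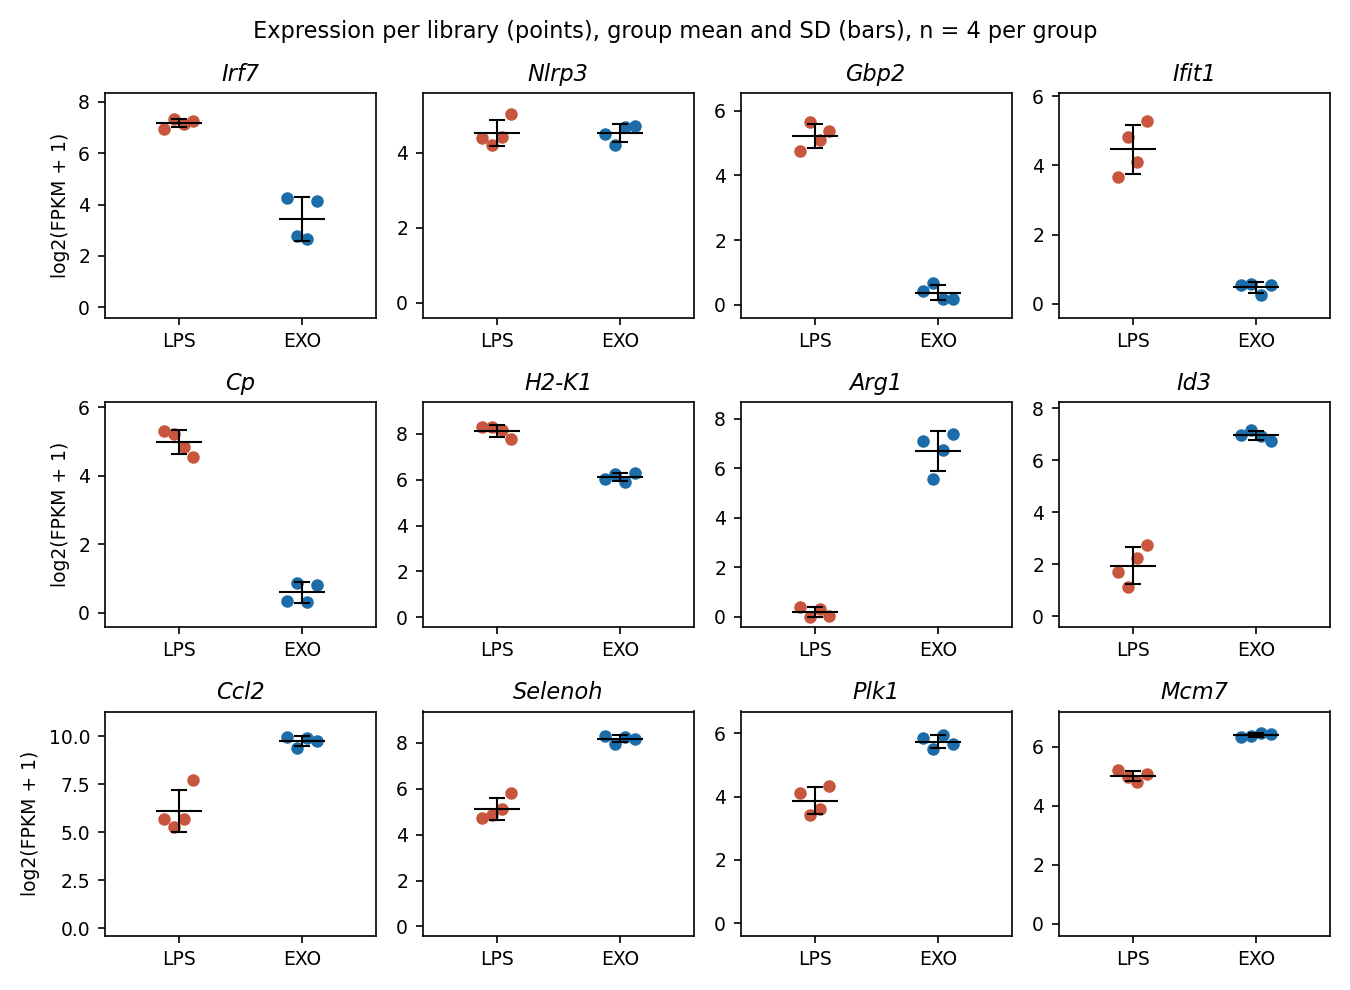
Expression of 12 genes in log2(FPKM + 1), 1 point per library (red LPS, blue EXO), with bars for the mean and SD of 4 libraries. Irf7, Gbp2, Ifit1, Cp and H2-K1 sit lower in all 4 EXO libraries, Arg1, Id3, Ccl2, Selenoh, Plk1 and Mcm7 sit higher, and Nlrp3 overlaps between the groups.

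Interferon-stimulated genes, the antiviral program that interferons switch on, were lower in EXO without exception among those tested. All 33 fell, over all genes and when adjusted over the list alone, with a median log2 fold change of -2.42. Gbp2, a guanylate-binding protein that acts on pathogen vacuoles, averaged 0.303 ± 0.220 in EXO and 37.3 ± 9.99 in LPS (log2 fold change -4.85, SE 0.18, limma adjusted p = 1.50e-09). Cmpk2, a nucleotide kinase, averaged 0.247 ± 0.153 and 16.7 ± 3.98, Zbp1, a sensor of Z-form nucleic acids, 0.105 ± 0.0846 and 11.1 ± 3.29, and Trim30a 2.30 ± 0.445 and 34.5 ± 8.21. A further 4 members were among the 10 lowest fold changes that the naming rule took. Ifit1, which binds viral RNA, averaged 0.392 ± 0.140 and 23.1 ± 11.6, and Rsad2 (viperin), an antiviral enzyme, 0.968 ± 0.341 and 28.6 ± 11.4. Rtp4 averaged 1.49 ± 1.04 and 34.5 ± 7.05, and Oasl2 1.23 ± 0.645 and 38.5 ± 8.14. The list shifted in the camera test (adjusted p = 5.58e-23), with an adjusted p = 0.115 with an estimated correlation, and no other of the 35 splits of the libraries gave a median as large (two-sided exact permutation p = 0.029, the smallest possible).

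Interferon receptors and the factors that regulate interferon were lower as well, by less. Of 18 tested, 11 fell, 1 rose and 6 were not called, the same counts as adjusted over the list alone, with a median of -0.50. Irf1, an interferon-induced transcription factor, averaged 3.34 ± 1.14 in EXO and 13.0 ± 1.38 in LPS. Ifngr1, a chain of the interferon gamma receptor, averaged 18.1 ± 1.09 and 45.9 ± 13.2, and Sting1, the adaptor of cytosolic DNA sensing, 18.7 ± 1.24 and 34.4 ± 0.847. Tyk2, a cytoplasmic kinase that binds cytokine receptors, averaged 4.20 ± 0.547 and 10.4 ± 0.563. The camera adjusted p was 3.02e-05, with an adjusted p = 0.0709 with an estimated correlation. Irf7 and Irf9 are in both this list and the list of interferon-stimulated genes.

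MHC class I presentation, by which cells display their own peptides, was lower in EXO. Of 16 tested genes 15 fell and 1 was not called, and 16 fell when adjusted over the list alone, with a median of -1.58 (camera adjusted p = 1.37e-10, and adjusted p = 0.0891 with an estimated correlation). The heavy chains H2-K1 and H2-D1 averaged 68.3 ± 8.72 and 146.0 ± 14.4 in EXO, against 281 ± 46.3 and 476 ± 73.1 in LPS. H2-T23 averaged 7.77 ± 2.42 and 54.4 ± 5.10, and H2-Q4 3.32 ± 0.940 and 22.9 ± 3.67. Of 4 tested class II genes, Ctss (cathepsin S), at 373 ± 32.7 and 916 ± 236, and Cd74 (the invariant chain), at 111 ± 39.0 and 269 ± 65.0, fell, and H2-DMb1, at 18.9 ± 1.69 and 23.3 ± 4.74, and H2-Oa, at 2.47 ± 0.546 and 2 ± 1.03, were not called, and adjusted over the list alone 2 fell. H2-DMb1 was called lower without LPS replicate 4 (limma adjusted p = 0.00707), without that library and EXO replicate 2 (0.00571) and after the GC content and length correction (0.0221). H2, Gbp and Oas genes have near-identical copies, and how shared fragments were assigned is not given in the sources used here, so their individual levels are uncertain.

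Inflammasome and pyroptosis genes were lower in EXO although Nlrp3 was not. Of 19 tested, 14 fell, 1 rose and 4 were not called, over all genes and over the list alone, with a median of -0.72. Il18, an inflammasome-processed cytokine, averaged 3.55 ± 0.690 in EXO and 22.6 ± 7.04 in LPS (log2 fold change -2.33, SE 0.20, limma adjusted p = 1.53e-06). Casp1, the inflammasome protease, averaged 69.9 ± 16.1 and 198 ± 35.8, and the flagellin sensors Naip5 and Naip6, near-identical copies, 1.39 ± 0.268 and 1.27 ± 0.0463 in EXO against 3.62 ± 0.286 and 3.43 ± 0.583 in LPS. Chosen after their values were seen, Pycard, the adaptor of the inflammasome, was the member that rose, from 29.3 ± 2.02 in LPS to 39.0 ± 6 in EXO, and Il1b averaged 37.1 ± 25.2 in EXO and 16.9 ± 5.15 in LPS without passing the test (limma adjusted p = 0.147). The camera adjusted p was 2.92e-05, with an adjusted p = 0.0891 with an estimated correlation.

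Inflammatory (M1-type) genes moved in both directions. Of 26 tested, 12 fell, 4 rose and 10 were not called, over all genes and over the list alone, with a median of -0.55. Acod1, the enzyme that makes itaconate, averaged 135 ± 40.8 in EXO and 600.4 ± 96.7 in LPS, and Cd40, a costimulatory receptor, 15.7 ± 3.32 and 53.9 ± 8.17. The members that rose were cytokines. Ccl2 and Ccl7, chemokines that recruit monocytes, averaged 876 ± 147 and 176 ± 26.9 in EXO, against 86.6 ± 81.3 and 7.59 ± 6.75 in LPS, where replicate 4 held 208 and 17.7 FPKM and the others 37.8 to 50.5 and 3.6 to 5.1. Csf3 (G-CSF), the neutrophil growth factor, averaged 6.81 ± 1.28 and 0.617 ± 0.391, and Ccl3, chosen after its values were seen, 856 ± 109 and 611 ± 260 (limma adjusted p = 0.0493). Also chosen after their values were seen, Tnf averaged 53.9 ± 14.3 and 65.0 ± 12.5 and Il6 51.2 ± 46.4 and 46.1 ± 56.6, and neither was called. The list shifted lower by camera (adjusted p = 0.0115), with an adjusted p = 0.441 with an estimated correlation, and 2 of the 35 splits gave a median as large (exact permutation p = 0.057). LPS replicate 4 lay a median of 0.49 above the other LPS libraries on this list, and without a filter on low values the list median was -0.16 and the camera adjusted p was 0.0524.

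Alternative activation (M2-type) genes did not move together, and Arg1 stood out among them. Arg1, arginase 1, averaged 113 ± 51.3 in EXO and 0.146 ± 0.161 in LPS, the highest fold change among the named genes (log2 fold change 6.51, SE 0.35, limma adjusted p = 1.42e-06), with 2708 to 9175 recovered fragments in EXO libraries and 0 to 19 in LPS libraries. Il1rn, the interleukin 1 receptor antagonist, averaged 77.1 ± 16.7 and 24.2 ± 6.12. Mrc1, the mannose receptor, averaged 2.05 ± 0.683 and 5.33 ± 1.02, and Il4ra, the interleukin 4 receptor, 3.57 ± 0.275 and 7.09 ± 1.31. Of 14 tested members 8 fell, 3 rose and 3 were not called, over all genes and over the list alone. The median was -0.32 and the mean 0.24, of opposite sign, and camera called no shift (adjusted p = 0.248, and adjusted p = 0.446 with an estimated correlation). No other of the 35 splits gave a median as large in size (exact permutation p = 0.029), the largest other being 0.278. Without a filter on low values the median was -0.15, and the log2 fold change of Arg1 by voom was 10.58.

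Toll-like receptor and NF-kB genes, which respond to microbial products, made up lists that shifted lower by camera with the preset correlation. Of 24 tested genes of LPS and Toll-like receptor signalling, 14 fell, 2 rose and 8 were not called, with a median of -0.49 (camera adjusted p = 1.30e-04, and adjusted p = 0.0891 with an estimated correlation). Tlr13, a sensor of bacterial ribosomal RNA, averaged 9.68 ± 1.61 in EXO and 42.0 ± 9.01 in LPS, Tlr7 8.85 ± 1.22 and 22.2 ± 3.89, Tlr2 37.7 ± 11.2 and 96.2 ± 8.49, and Tlr1 7.31 ± 0.795 and 18 ± 3.18. In the NF-kB pathway, 11 of 23 tested genes fell, 1 rose and 11 were not called, with a median of -0.43 (camera adjusted p = 0.00213, and adjusted p = 0.385 with an estimated correlation). Icam1, an adhesion molecule, averaged 11.5 ± 0.590 and 39.4 ± 10.2, Tnfaip3 (A20), a feedback inhibitor of NF-kB, 3.75 ± 1.21 and 13.2 ± 1.01, Birc3 18.7 ± 4.91 and 44.0 ± 0.994, and Tnfaip2 36.8 ± 10.1 and 86.3 ± 5.40. The counts of both lists were the same when adjusted over the list alone.

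The remaining genes with the highest fold changes belonged to several families. Id3 and Id1, inhibitors of helix-loop-helix transcription factors, averaged 124 ± 15.2 and 22 ± 12.1 in EXO and 3.22 ± 1.99 and 0.676 ± 0.327 in LPS (log2 fold changes 5.01 and 3.65). Cxcl14, a chemokine, averaged 22.9 ± 6.38 and 0.753 ± 0.533. Dmpk, a protein kinase, and Dmwd, its neighbour on the chromosome, averaged 12.2 ± 4.15 and 18.7 ± 4.48 in EXO and 0.0369 ± 0.0344 and 0.488 ± 0.381 in LPS. Neighbouring genes can share fragments, and the strand setting of the counting is not given in the sources used here. Selenoh, a nuclear selenoprotein, averaged 289.9 ± 29.5 and 35.5 ± 13.6, and Cstdc4, a cystatin of a family of near-identical copies and so uncertain, 8.25 ± 5.13 and 0.0149 ± 0.0297. Each passed with a limma adjusted p of at most 3.35e-04.

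At the low end, genes outside the interferon list were Cp, Ms4a6b, Cfb and Ifi205. Cp (ceruloplasmin), a copper-carrying ferroxidase, averaged 0.539 ± 0.311 in EXO and 31.4 ± 7.57 in LPS (log2 fold change -4.39, SE 0.18, limma adjusted p = 3.97e-09). Cfb, complement factor B, averaged 0.993 ± 0.525 and 37.7 ± 14.9. Ms4a6b averaged 0.428 ± 0.235 and 27.8 ± 11.5, and Ifi205 0.195 ± 0.0699 and 16.8 ± 6.94, both members of families with near-identical copies and so uncertain.

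Genes of the cell division cycle were higher in EXO. All 25 tested genes of the G2 and M phases rose, with a median of 1.18 (camera adjusted p = 5.65e-10, and adjusted p = 0.278 with an estimated correlation). Plk1, a mitotic kinase, averaged 52.9 ± 7.48 in EXO and 14.1 ± 4.43 in LPS, Cks2 149 ± 26.6 and 40.5 ± 7.80, Ccnb2 (cyclin B2) 63.2 ± 11.3 and 20.3 ± 3.42, and Birc5 (survivin) 43.3 ± 3.41 and 18.5 ± 2.73. On this list LPS replicate 4 lay a median of 0.44 above the other LPS libraries. Of 25 tested S phase genes, 21 rose and 4 were not called, with a median of 0.89 (camera adjusted p = 5.90e-07, and adjusted p = 0.278 with an estimated correlation). Mcm7, a subunit of the replicative helicase, averaged 83.5 ± 3.59 and 31.6 ± 3.85, Cdt1 57.0 ± 6.15 and 21.7 ± 3.04, and Tyms (thymidylate synthase) 18.1 ± 1.41 and 7.11 ± 1.04. The counts were the same over each list alone.

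Among genes of energy metabolism, the nuclear genes of oxidative phosphorylation were slightly higher. Of 31 tested, 16 rose and 15 were not called, or 15 rose adjusted over the list alone, with a median of 0.30. Cyc1 (cytochrome c1) averaged 107 ± 8.11 in EXO and 60.7 ± 7.13 in LPS, Ndufs8 111 ± 10.1 and 67.2 ± 2.75, Uqcrc1 154 ± 12.7 and 94.8 ± 8.87, and Ndufa4 781 ± 111 and 454 ± 53.7. The list's camera adjusted p was 0.00861, with an adjusted p = 0.492 with an estimated correlation and 0.0597 without LPS replicate 4 (median 0.26). Under median-of-ratios rescaling the median was 0.19.

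Glycolysis and hypoxia genes showed no list-wide shift. Of 18 tested glycolysis genes 3 rose, 1 fell and 14 were not called (2 and 1 over the list alone), with a median of 0.21 (camera adjusted p = 0.474, and adjusted p = 0.859 with an estimated correlation). The median was 0.10 under rescaling, 0.092 without EXO replicate 4, 0.33 without EXO replicate 2 and 0.35 without EXO replicate 2 and LPS replicate 4. Ldha, lactate dehydrogenase, averaged 504 ± 93.9 and 300.5 ± 33.6, Eno1 592 ± 89.1 and 384 ± 74.4, and Pfkfb3 5.64 ± 0.311 and 9.62 ± 0.514. Pkm averaged 452 ± 68.6 and 361 ± 36.2 with a limma adjusted p of 0.0461, which rose above the threshold without any of EXO replicates 1, 3 and 4 or LPS replicates 1, 2 and 3 (0.0647 to 0.166), without a filter on low values (0.085) and under rescaling (0.158). Of 17 tested hypoxia genes 3 rose, 2 fell and 12 were not called (1 and 1 over the list alone), with a median of 0.14 (camera adjusted p = 0.920, and adjusted p = 0.965 with an estimated correlation). Kdm3a, a histone demethylase, averaged 5.34 ± 0.454 and 11.6 ± 1.05, and Higd1a 35.4 ± 8.37 and 23.5 ± 2.99. Stc2 averaged 17.5 ± 3.17 and 9.98 ± 4.48 and Ddit4 13.6 ± 2.99 and 9.83 ± 1.6, with limma adjusted p of 0.02 and 0.0373. The call of Stc2 was lost without EXO replicate 3 or 4 (0.0560 and 0.0538), and that of Ddit4 without any of EXO replicates 1, 2 and 4 or LPS replicates 1, 2 and 3 (0.0550 to 0.120). Both were lost without a filter on low values (0.0555 and 0.106), and that of Ddit4 also under rescaling (0.092) and after the GC content and length correction (0.116). The median stayed above 0 while the camera direction turned in 4 of the leave-one-out fits and under rescaling (median 0.035).

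Lists that track RNA quality differed little. Of 13 mitochondrially encoded mRNAs 2 fell and 11 were not called, with 0 adjusted over the list alone by limma and a median of -0.16 (camera adjusted p = 0.292, and adjusted p = 0.812 with an estimated correlation). The median ranged over the alternatives from -0.37 without EXO replicate 2 and LPS replicate 4 to -0.013 without LPS replicate 2. ND4 averaged 1293 ± 140 in EXO and 1722 ± 394 in LPS, ND5 2037 ± 268 and 2563 ± 673, ND4L 22.5 ± 2.39 and 30.6 ± 6.64, and ND6 194 ± 78.3 and 112 ± 24.4. The calls of ND4 and ND4L were lost without LPS replicate 2 (limma adjusted p of 0.135 and 0.0784) or EXO replicate 4 (0.115 and 0.0747), that of ND4 also without EXO replicate 1 (0.0539). Both were lost without a filter on low values (0.089 and 0.0616), and that of ND4L with voom (0.0699). ND6 was called higher without EXO replicate 4 or LPS replicate 2 (8.71e-04 and 0.0448) and after the GC content and length correction (0.00983). Of 30 cytosolic ribosomal protein genes 8 rose and 22 were not called, or 4 rose over the list alone, with a median of 0.13 (camera adjusted p = 0.248, and adjusted p = 0.837 with an estimated correlation). That median was 0.020 under rescaling, 0.019 after the GC content and length correction and 0.056 without LPS replicate 4. Rps2 averaged 3304 ± 493 and 1967 ± 172, Rpl8 2525 ± 329 and 1572 ± 111, Rpl15 560.1 ± 53.1 and 407 ± 40.4, and Rpl18 999 ± 92.3 and 764 ± 97.1, whose call was lost under median-of-ratios rescaling (limma adjusted p = 0.119).

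Lipid genes were lower in EXO. Of 23 tested genes of cholesterol synthesis and uptake, 21 fell and 2 were not called, the same over the list alone, with a median of -0.79 (camera adjusted p = 8.28e-07, and adjusted p = 0.385 with an estimated correlation). The sterol enzymes Mvd, Nsdhl and Tm7sf2 averaged 13.2 ± 2.85, 7.99 ± 1.03 and 1.63 ± 0.214 in EXO, against 40.8 ± 8.68, 24.0 ± 5.89 and 5.74 ± 1.79 in LPS. LPS replicate 4 lay a median of 0.54 above the other LPS libraries on this list. Of 18 tested genes of LXR targets and lipid handling, 15 fell and 3 were not called, or 16 fell over the list alone, with a median of -1.04 (camera adjusted p = 4.05e-07, and adjusted p = 0.0891 with an estimated correlation). Lpl, lipoprotein lipase, averaged 109 ± 23.4 and 503 ± 108, Plin2, a lipid droplet coat protein, 26.4 ± 2.25 and 104 ± 13.5, and the desaturases Scd1 and Scd2 4.14 ± 1.39 and 79.1 ± 14.1 in EXO against 26.3 ± 4.30 and 224 ± 47.7 in LPS.

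Lysosome and phagocytosis genes were also lower. Of 23 tested, 20 fell, 2 rose and 1 was not called, or 21 fell over the list alone, with a median of -0.71 (camera adjusted p = 2.23e-06, and adjusted p = 0.225 with an estimated correlation). Lamp2, a lysosomal membrane protein, averaged 57.2 ± 6.43 in EXO and 126 ± 10.6 in LPS, Ctsz, a cathepsin, 373 ± 44.0 and 702 ± 47.1, and Grn, progranulin, 153 ± 28.0 and 303 ± 8.14. Chosen after their values were seen, the members that rose were Ctsl, a cathepsin, at 318 ± 66.7 and 166 ± 13.4, and Cd9, a tetraspanin also abundant on exosomes, at 169 ± 14.4 and 113 ± 15.7. Cd63 and Cd81, other tetraspanins of exosomes chosen in the same way, fell, averaging 56.0 ± 8.26 and 30.7 ± 3.03 in EXO against 106 ± 14.2 and 44.2 ± 4.72 in LPS.

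Members of the stress lists moved in both directions. Among 22 tested genes of ER stress and the integrated stress response, 11 fell, 5 rose and 6 were not called, over all genes and over the list alone, with a median of -0.54. Among those with the smallest p, the chaperone genes Calr and Dnajb9 averaged 228 ± 16.6 and 6.25 ± 0.575 in EXO and 515 ± 81.8 and 16.6 ± 2.99 in LPS, Edem1, of ER-associated degradation, 20.2 ± 3.64 and 53.2 ± 4.03, and the transcription factor Xbp1 26.5 ± 1.70 and 51.2 ± 3.25. Chosen after their values were seen, the members that rose were Atf4, a transcription factor of the integrated stress response, and Chac1, Asns, Psat1 and Shmt2. Asns, asparagine synthetase, averaged 102 ± 12.7 and 59.1 ± 17.7, Shmt2, a mitochondrial enzyme of serine metabolism, 194 ± 11.6 and 74.8 ± 25.7, and Atf4 333 ± 13.4 and 243 ± 81.3. The camera adjusted p was 0.0319, with an adjusted p = 0.663 with an estimated correlation and 0.108 by fry. LPS replicate 4 lay a median of 0.58 above the other LPS libraries on this list, and without it the median was -0.29 and the camera adjusted p 0.0982, or -0.40 and 0.0821 without EXO replicate 2 as well.

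Among 21 tested NRF2 antioxidant genes 8 fell, 2 rose and 11 were not called (7 and 2 over the list alone), with a median of -0.17 (camera adjusted p = 0.0354, and adjusted p = 0.385 with an estimated correlation). Srxn1, sulfiredoxin, averaged 17.3 ± 3.02 in EXO and 75.3 ± 16.0 in LPS, Cat, catalase, 31.2 ± 6.74 and 83.9 ± 14.1, Me1 4.69 ± 0.969 and 13.6 ± 1.44, and G6pdx 100.2 ± 12.3 and 198 ± 21. Of the 35 splits of the libraries, 8 gave a median as large (exact permutation p = 0.229). The list's median moved to -0.11 without LPS replicate 3, -0.039 without LPS replicate 4, -0.28 under rescaling and -0.26 with voom, and its call was lost without EXO replicate 4 (camera adjusted p = 0.0569).

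Of 19 tested p53 targets and apoptosis genes, 12 fell, 1 rose and 6 were not called, the same over the list alone, with a median of -0.46 (camera adjusted p = 3.56e-04, and adjusted p = 0.0721 with an estimated correlation), or -0.28 without EXO replicate 2 and LPS replicate 4. Fas, a death receptor, averaged 4.89 ± 0.747 in EXO and 26.3 ± 6.70 in LPS, Pmaip1 (Noxa) 9.65 ± 1.93 and 32.1 ± 5.99, Sesn1 5.80 ± 0.171 and 16.7 ± 3.47, and Trp53inp1 0.251 ± 0.0311 and 2.52 ± 0.373. Immediate early genes went both ways, with 6 of 17 tested higher, 7 lower and 4 not called, over all genes and over the list alone. Klf2 averaged 3.80 ± 0.534 and 9.21 ± 1.78, Dusp1 5.90 ± 1.19 and 12.5 ± 3.12, Btg2 3.92 ± 0.704 and 7.09 ± 0.360, and Nr4a1 1.46 ± 0.303 and 0.416 ± 0.0870. That list's median was -0.11 and its mean 0.034, of opposite sign, and camera called no shift (adjusted p = 0.345, and adjusted p = 0.777 with an estimated correlation). The median ranged from -0.50 with a mean FPKM of at least 5 to -0.034 without a filter on low values.

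**Figure D3:**
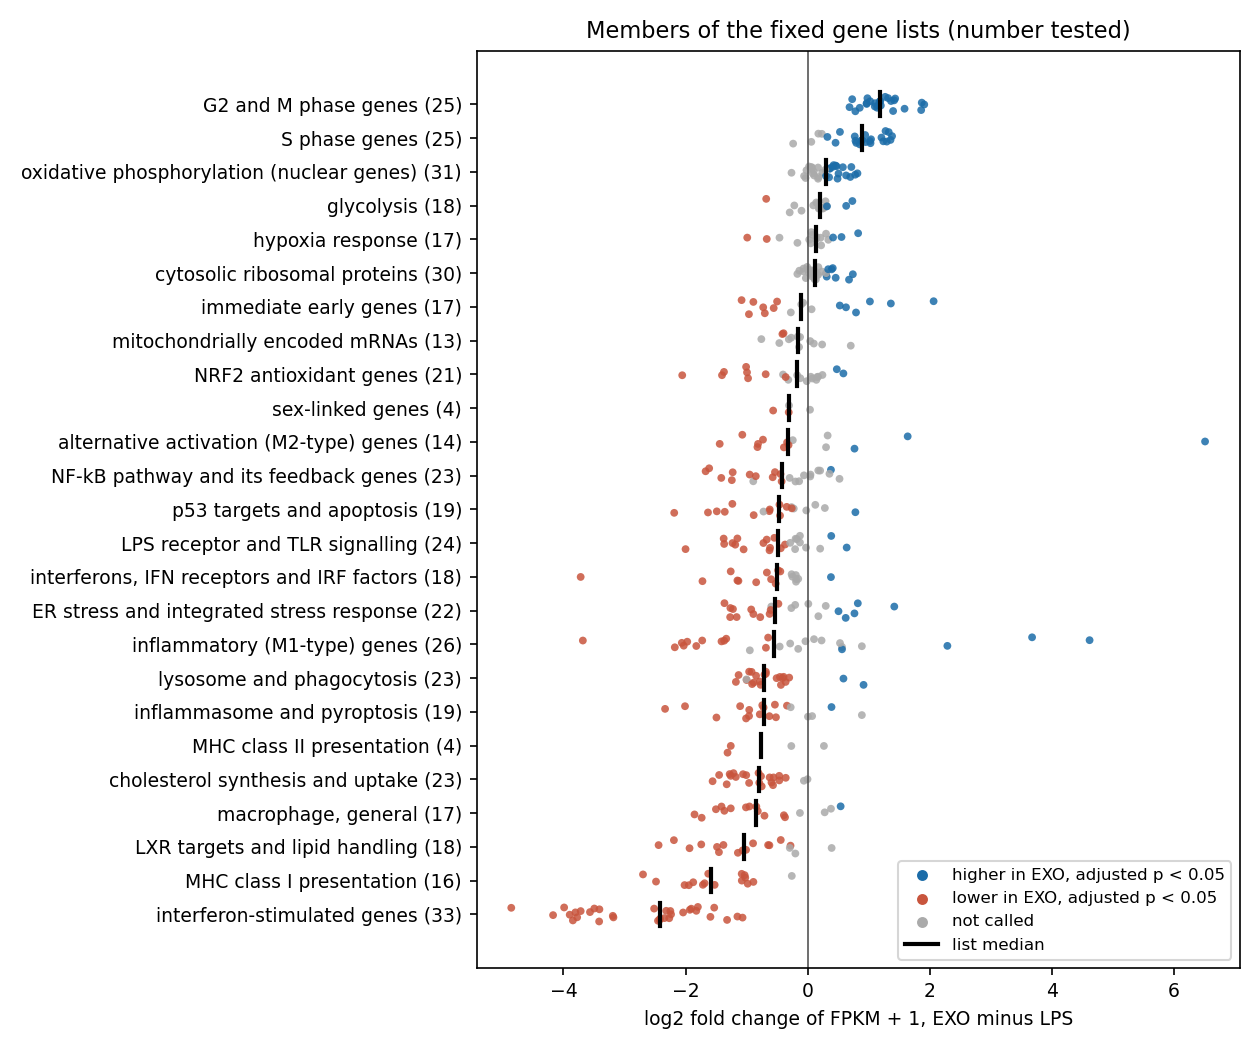
Log2 fold change of FPKM + 1, EXO minus LPS, for each tested member (points) of the pathway and quality lists and of the general macrophage markers, with the number tested in brackets and the median as a black bar. Blue and red points passed an adjusted p of 0.05 as higher and lower in EXO, and list medians run from 1.18 for the G2 and M phase genes to -2.42 for the interferon-stimulated genes.

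By camera with the preset correlation, 16 of the 22 lists shifted, 3 higher and 13 lower in EXO, and fry called 15. With an estimated correlation 0 lists passed after adjustment and 7 had an unadjusted camera p under 0.05.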

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

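The tests on LPS replicate 4 were chosen only after the result was seen. Among 260 groups of 4 values, 19 held a value that stood far from the others (Dixon's test at its 95% critical value), where chance gives about 1 in 20 groups, or 13. Of these, 7 were high values in LPS replicate 4, among them, in FPKM, Ccl7 at 17.7 (others 3.6 to 5.1), Dmwd at 1.06 (0.251 to 0.353), Ccl2 at 208 (37.8 to 50.5), Cd40 at 66.1 (48.5 to 50.9), Il1rn at 33.3 (20 to 22) and Icam1 at 54.7 (33.6 to 35.8). In LPS replicate 2, H2-Q4 stood at 28.4 (21 to 21.2), Trp53inp1 at 3.08 (2.28 to 2.37), ND4 at 2310 (1470 to 1600) and ND5 at 3570 (2190 to 2260). Tyk2 stood at 11.2 in LPS replicate 3 (10 to 10.2), and in LPS replicate 1 Fabp4 stood at 7.76 (12.9 to 13.8) and Lpcat1 at 8.21 (5.4 to 5.87). In EXO, Acod1 stood at 196 (110 to 120) and Fas at 6.0 (4.42 to 4.61) in replicate 2, Birc5 at 48.3 (41.2 to 41.9) and Fabp4 at 7.74 (3.77 to 4.08) in replicate 1, and Edem1 at 25.6 (18 to 19.0) in replicate 4.

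LPS replicate 4 lay nearest EXO on the first principal component, and its high Ccl2 and Ccl7 go the same way. RNA or reads carried over from EXO libraries would bring every EXO transcript in proportion, but Arg1 held 1 fragment there, 0.0365% of its level in the lowest EXO library, while the excess of Ccl2 was 18.5% of the EXO mean. A weaker LPS response there would lower interferon-stimulated genes, but they lay a median of 0.394 above LPS replicates 1 to 3 on the log2 scale. ER stress genes (0.583), cholesterol genes (0.542) and M1-type genes (0.493) were also above, and ribosomal protein genes below (-0.333). What set this library apart was not tested further.

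The interferon-stimulated genes lay lower in EXO by a list median of -2.423, and by -2.373 after a correction for GC content and gene length, which argues against such a bias. Unequal scaling of libraries would move all genes by about the shift, but the median of all genes was only 0.085 before rescaling. Rescaling sets that median near 0 by construction (-0.005), and the list median was then -2.51. A subclone with other chromosome copy numbers would move whole chromosomes, but their median fold changes ran only from -0.054 to 0.144. The list median was -2.559 after subtracting them, though subtracting such small values could not have removed the shift. These medians cannot show a subclone without such copy changes. Under the design, the groups differ in treatment with ADSC-Exos, and an effect of it on interferon signalling may be the source. Whether the EXO libraries also received LPS is not stated, so a lower LPS stimulus remains open and untested.

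Of the selenoprotein genes, Selenoh (log2 fold change 3.06) and Selenow (2.05, from 37.8 ± 6.41 FPKM in LPS to 158 ± 19.0 in EXO, chosen after its values were seen) lay higher in EXO. A GC content or gene length bias is argued against, since the lower of the corrected values was 1.856. A greater selenium supply would raise Gpx1 and Msrb1, whose mRNAs are selenium-sensitive. Gpx1 was at 1.24 (limma adjusted p = 3.24e-06), while Msrb1 was at -0.315 and not called (limma adjusted p = 0.131). After the GC content and length correction Msrb1 was at -0.427 (limma adjusted p = 0.0349). The 2 genes disagree, so they do not decide whether selenium supply differed. Of the other 14 tested selenoprotein genes, 6 were higher and 3 lower, with a median of 0.211. An effect of the treatment on these genes may be the source and was not tested.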

How the results depend on the processing

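The rescaling, the mean FPKM filter, voom, the GC content and length correction (alone and with the block), the fit without EXO replicate 2 and LPS replicate 4 and the CPM minimum of 10 were chosen after the data were seen. In every setting of limma the calls shared with the reported test had the same direction. Between 2849 and 3652 genes were higher and between 2005 and 2975 lower in every setting but a mean FPKM of at least 5. Higher calls outnumbered lower ones except under rescaling (2849 against 2975). With that mean filter fewer genes were tested, and 2485 and 1685 were called. Leaving out 1 library at a time gave 2867 to 3652 higher and 2005 to 2385 lower genes, 14 to 16 shifted lists, and log2 fold changes of -3.980 to -3.451 for Irf7 and -0.096 to 0.175 for Nlrp3. Nlrp3 was -0.097 under rescaling and 0.281 (limma adjusted p = 0.0484) without EXO replicate 2 and LPS replicate 4. Camera with an estimated correlation called 0 lists, 7 having an unadjusted p under 0.05, against 16 with the preset one. The lists of interferon receptors and factors and of p53 targets also lost their calls. Their estimated correlations were -0.004 and -0.003, so a correlation above the preset 0.01 cannot be the cause for them. The other tested lists had estimates above the preset one. Otherwise the cause was not tested.

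The camera direction of the hypoxia list turned, at medians of 0.147 and 0.030 without EXO replicate 1 or 4, 0.051 and 0.146 without LPS replicate 2 or 4, 0.035 under rescaling and 0.142 with the mean filter, in a leave-one-out range of 0.030 to 0.191. Signs turned for Kdm5d (leave-one-out range -0.016 to 0.081, rescaled -0.045), Batf3 (leave-one-out range -0.127 to 0.160, without EXO replicate 2 and LPS replicate 4 0.171) and S100a8 (-0.022 in that fit). The cause was not tested. Of the other gene values, 2010 kept direction and call, 37 lost and 12 gained a call. Of the list values, 390 kept and 22 lost a call. At a mean CPM of at least 1, 18 macrophage and 0 epithelial markers were present, and 16 and 0 at 10.

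The replicate number as a block gave 3253 higher and 2339 lower genes, and 3370 and 2354 with the GC content and length correction, with 16 lists each time. Same-numbered libraries correlated by 0.045, 0.17, -0.292 and -0.109 in their deviations from group means, and not every library correlated best with its own number. These values give no sign of pairing by number. With so few libraries they cannot exclude it, and the labels do not state it. The block alone changed no call of a named gene. The planned count-based tests and normalizations were not run. Voom on the recovered counts was run in their place. The depth of 37061712 to 40640973 fragments limits genes of low FPKM, and those at 1 FPKM or more in fewer than 4 libraries were outside the reported test.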

Other observations

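Several gene sets from the KEGG and GO columns shifted higher in EXO by camera with the preset correlation. Of 123 tested genes of the spliceosome, 93 rose and 1 fell, with a median log2 fold change of 0.595 (camera adjusted p = 8.12e-10, and adjusted p = 0.616 with an estimated correlation). Of 70 genes of ribosome biogenesis 56 rose and 0 fell by limma (median 0.717, camera adjusted p = 5.61e-08, and adjusted p = 0.623 with an estimated correlation), and of 94 genes of mitochondrial translation 80 rose and 0 fell (0.621, camera adjusted p = 2.3e-10, and adjusted p = 0.774 with an estimated correlation). Of 35 DNA replication genes 32 rose (0.949, camera adjusted p = 7.64e-09, and adjusted p = 0.356 with an estimated correlation), and of 44 aminoacyl-tRNA biosynthesis genes 34 rose (0.552, camera adjusted p = 7.06e-06, and adjusted p = 0.616 with an estimated correlation).

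Other sets shifted lower in the same test. Of 22 tested pattern recognition receptors 20 fell and 1 rose (median -1.278, camera adjusted p = 1.16e-08, and adjusted p = 0.632 with an estimated correlation), of 18 cytokine receptors 16 fell (-1.115, camera adjusted p = 1.99e-06, and adjusted p = 0.699 with an estimated correlation), and of 35 genes of sphingolipid metabolism 26 fell and 1 rose (-0.558, camera adjusted p = 3.55e-06, and adjusted p = 0.267 with an estimated correlation). These sets, from the KEGG and GO columns of the deposited table, were tested only after the data were seen, as were the permutations of list medians. Camera with the preset correlation called 21 higher and 98 lower of 299 KEGG sets and 277 higher and 376 lower of 2633 GO sets. With an estimated correlation it called 0 of each, with 42 and 174 at an unadjusted p under 0.05.

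Chosen after their values were seen, other genes near the strongest ones were compared. Id2, a relative of Id1 and Id3, averaged 28.6 ± 2.50 FPKM in EXO and 15.7 ± 3.06 in LPS, and Smad6, like Id1 and Id3 a known target of bone morphogenetic protein signalling, 3.82 ± 0.664 and 0.5 ± 0.178 (limma adjusted p of 1.14e-04 and 1.76e-07). Smad7 averaged 0.701 ± 0.21 and 0.258 ± 0.151, Smad9 0.881 ± 0.178 and 0.0319 ± 0.0237 and Atoh8 0.0815 ± 0.0112 and 0.0538 ± 0.0513, all below the filter and untested, and Id4 and Bambi are not analysed here. The metallothioneins Mt1 and Mt2 averaged 211 ± 60.2 and 146 ± 39.6 in EXO against 70.6 ± 27.0 and 37.4 ± 37.5 in LPS. Around the neighbours Dmpk and Dmwd, Sympk rose by 0.60 and Fbxo46 by 0.61 on the log2 scale, while Qpctl was not called (-0.092), and Six5, below the filter and untested, averaged 0.510 ± 0.171 and 0.261 ± 0.142. Arg1 was the 1 gene at 10 FPKM or more in every EXO library and under 1 in every LPS library, and 7 genes showed the opposite (Cmpk2, Cp, Gbp2, H2-T24, Ifi205, Ifit1 and Ms4a6b).

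Chance as the source of the counts was tested by the 35 splits of the 8 libraries into 4 and 4. Only 1 of the 35, the real split, gave as many higher genes (3310) or lower genes (2422). That share, an exact permutation p of 0.029, is the smallest that 35 splits can give. The highest other split gave 0 by limma, with up to 1758 in a direction at an unadjusted p under 0.05. Every other split puts EXO and LPS libraries in the same group, so their difference widens the spread within groups. The 0 therefore adds little. Chance is an improbable source of both counts if the libraries are independent samples, which the labels do not say. For the number of lists shifted by camera, the splits do not exclude chance and cannot decide it. There 9 of the 35 splits gave at least the real 16, and the highest other split gave 20. Splits that keep most EXO libraries together still hold part of the group difference, which camera can call. With fry the real split gave 15 and the highest other 0, which adds little for the same reason as the 0 by limma.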
